A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

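The deposited values were counts per annotated gene feature, 1 table per library, whole numbers. Per the submitters' processing notes, reads were made with CASAVA 1.8.2, STAR, featureCounts of Subread 1.5.0-p1 and DESeq2 on build R64. The aligner's options, the strand setting and the treatment of reads with several positions were not given in the sources used here. The labels describe UV cross-linking, immunoprecipitation for 4 h with 5 washes, 500 ng of RNA as input, fragments of 200 bp and no depletion of rRNA. Raw reads were not used here.

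Features were joined to gene symbols by locus tag (6048), by symbol or synonym (121) or not at all (957), and coordinates and lengths came from the same reference table. The 12 libraries were assigned to 6 groups of 2 by the labels. Total counts ranged from 87741 to 1140349 per library, and the rRNA features together held 30 counts.

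Tests used R 4.3.3 with edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest), TMM scaling and filterByExpr with a minimum of 10 counts and 15 in total, which left 5245 features. All 12 libraries were in the fit, with 1 mean per group and 6 residual degrees of freedom, and the common biological coefficient of variation was 0.356. Benjamini-Hochberg adjustment at 0.05 was applied within each of 10 comparisons: each protein against the no-tag control at each temperature, the heat change in each strain, and 3 interactions. Gene lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over all 150 tests, and with an estimated correlation. The 15 lists were amino acid biosynthesis, cell wall, cytosolic ribosomal proteins, general stress, glycolysis, heat shock proteins, histones, mitochondrial genome, mRNA export, oxidative phosphorylation, proteasome, ribosome biogenesis, snoRNA and snRNA, strain markers and translation factors. CPM were scaled with TMM, and log2 values for single libraries used a prior count of 2. The SE of a log2 change was its size divided by the square root of its F statistic. It thus rests on the spread over all 12 libraries of the fit, moderated across genes, and not on the compared libraries alone.

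Genes were named by a rule: the 10 highest and 10 lowest called genes with a mean of at least 50 counts and no overlap between groups, up to 2 highest and 2 lowest members of each list, and 14 fixed genes. Not every gene under the rule is in the text, and those with 1 to 3 counts in the control are given without a fold. The lists, this rule, the comparisons and the alternatives were fixed before the data were examined, except where a choice is said to have followed the values.

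The growth protocol says that each culture was divided between 25 °C and 42 °C, so a fit with the culture as a block (the paired fit) was run for the heat comparisons. The correlation of the deviations of replicate 1 from replicate 2 over 2247 genes was 0.266, 0.114 and 0.601 between the temperatures of no tag, Npl3 and Mex67, and −0.174 to 0.455 between different strains. The sources used here do not say that the numbers pair libraries of different strains, and these correlations did not settle it. STE2 was higher in replicate 2 of all 6 groups, so the numbers may carry a shared difference, and a block for them was run as an alternative.

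Alternatives were DESeq2 1.42.0, RLE size factors, total counts only, protein-coding genes only, no low-count filter, a mean of at least 50 counts, only the groups compared, both blocks and leaving out each of the 12 libraries. After the data were seen, limma voom with sample weights, edgeR with bias-adjusted deviances, offsets corrected for gene length (lowess on log10 length per library, span 0.4), the same with the culture block, and fry were added. GC content was not analysed here.

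The methods were tested on simulated data with the dispersions of the fit, 3 data sets of 200 planted genes per design. For Npl3 at 25 °C, 33% of planted 4-fold changes and 3.33% of 2-fold changes were recovered. For the Mex67 heat change, 23% of 4-fold changes were recovered without pairing and 36.3% with the culture block. The false calls were 1 of 25 without pairing and 5.33 of 42.7 with the culture block on average. The simulated paired calls thus held a larger share of false ones than the threshold of 0.05. These libraries were drawn without an effect of culture. They therefore show neither the gain nor the error of pairing where cultures differ, as the correlation of 0.601 for Mex67 leaves possible. Of 200 random lists 2% had an unadjusted p under 0.05 with camera. The simulated genes were drawn independently, so this does not test lists whose genes vary together between libraries. A simulated length trend without other change gave 30 calls, and 1 after the length correction. The overlap that a shared control gives was taken from 20 simulations without enrichment. Figures were drawn with matplotlib 3.10.9.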

Results

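RNA attached to the mRNA export receptor Mex67 and to the mRNA-binding protein Npl3 of budding yeast was sequenced after UV cross-linking and immunoprecipitation, with a control without a tag taken through the procedure as the background. The labels name 2 strains for this control without saying which library came from which, and c-myc and GFP-Trap beads without saying which samples were taken through which. A difference in strain or beads would lie under every comparison between the proteins and with the control. Each strain was sampled at 25 °C and after 30 min at 42 °C, which gave 6 groups of 2 libraries. The series design calls the 2 libraries of a group biological replicates, so the p-values of single genes measure the spread between these samples. Genes of a single mating type differed between the replicates (below), so this spread may include a difference in strain. The camera p-values with the preset correlation do not measure how the genes of a list vary together between libraries. The no-tag libraries held 684839 and 363586 counts at 25 °C and 87741 and 485848 counts at 42 °C (replicates 1 and 2). The Npl3 libraries held 742758 and 1140349 counts at 25 °C and 778484 and 1011990 at 42 °C. The Mex67 libraries held 354440 and 422858 counts at 25 °C and 889402 and 449513 at 42 °C. Of the counted features, 5245 had enough counts to be tested.

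Messages of nuclear protein-coding genes made up 77.1% ± 10.1 (SD, n = 2) of the counts in the no-tag libraries at 25 °C, 87.6% ± 0.268 in the Npl3 libraries and 83.2% ± 1.02 in the Mex67 libraries. At 42 °C the shares were 66.3% ± 15.7, 83.5% ± 1.13 and 82.3% ± 10.4. Small nucleolar and small nuclear RNAs, which guide rRNA modification and splice messages, took 15% ± 9.66 of the no-tag counts, 7.74% ± 1.35 of the Npl3 counts and 8.89% ± 0.35 of the Mex67 counts at 25 °C. Their shares at 42 °C were 21.8% ± 12.1, 10.8% ± 0.199 and 11.2% ± 6.72. The spread between the no-tag replicates was larger than most of these differences. The RNA of the signal recognition particle ranged from 2.27% ± 0.939 (Npl3, 25 °C) to 8.22% ± 4.08 (no tag, 42 °C), and transcripts of the mitochondrial genome from 1.92% ± 0.063 to 2.91% ± 0.3.

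HSP26, a small heat shock protein gene (YBR072W, build R64, chromosome II, 382030 to 382674), separated most heated libraries from the unheated ones. It lay between 56.7 and 633 CPM (counts scaled to library size with TMM) in the 6 libraries at 25 °C and between 3544 and 10310 in 5 of the 6 libraries at 42 °C. The remaining heated library, no-tag replicate 1, had 300.4 CPM of HSP26 and 300.4 of HSP12, a membrane-protecting stress protein gene. Its own culture at 25 °C had 56.7 CPM of HSP26 (32 counts, against 18 in the smaller heated library) and 253 CPM of HSP12, and the other heated libraries had 2149 to 5727. The median change of 70 general stress genes from the same culture at 25 °C was −0.90 (log2) in that library and 0.48 to 1.2 in the other 5. It was also the smallest library, and both comparisons with the no-tag control at 42 °C, the heat change of the control and the interactions with it rest partly on it.

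**Figure D1:**
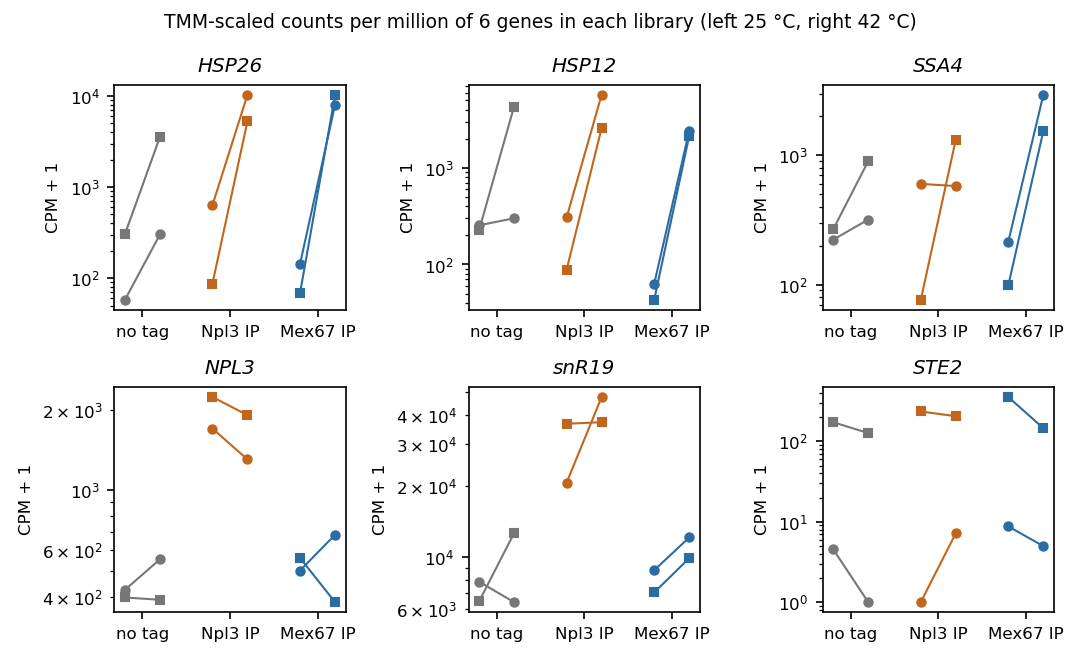
TMM-scaled CPM (plus 1, log axis) of 6 genes in each of the 12 libraries; lines join the 25 °C and 42 °C libraries with the same replicate number (circles, replicate 1; squares, replicate 2). HSP26 reached 3544 or more in 5 of the 6 heated libraries and 300.4 in no-tag replicate 1.

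Replicates also differed in genes that only 1 mating type expresses. STE2, the pheromone receptor gene of a cells, stood at 0 to 7.73 CPM in replicate 1 of all 6 groups and at 126 to 354 in replicate 2. STE3, the receptor gene of alpha cells, stood at 356 and 334 CPM in the no-tag libraries at 25 °C, at 2.77 and 12 in the Npl3 libraries and at 201 and 23.3 in the Mex67 libraries. LEU2, a leucine synthesis gene used as a strain marker, stood at 1374 CPM in no-tag replicate 1 and at 11.8 in replicate 2 at 25 °C. These 3 genes were chosen after their values were seen. The list of 17 strain marker genes passed in 0 of the 10 comparisons (camera, lowest adjusted p = 0.212). It holds genes of both mating types, and camera asks for a shared direction between groups. This result therefore does not speak to the differences above.

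Fixed gene lists were tested in 10 comparisons each with camera, and 77 of the 150 tests had an adjusted p under 0.05 with the preset correlation between genes. With a correlation estimated from the libraries 0 passed, the lowest adjusted p being 0.69, so every list call below was lost with an estimated correlation. Lists that kept their call without any 1 library were favoured for the text after those fits were seen, and the others are given with the library that ended the call. By list, ribosome biogenesis (lowest adjusted p = 1.3e-26), cytosolic ribosomal proteins (4.3e-45) and proteasome genes (2.3e-12) passed in 9 comparisons each, and amino acid biosynthesis passed in 8 (1.1e-12). General stress genes passed in 7 (4.4e-11) and translation factors in 6 (4.1e-10). SnoRNAs and snRNAs (3.5e-26), heat shock proteins (2.7e-09) and oxidative phosphorylation (5.8e-09) passed in 5 each. Glycolysis (4.8e-04) and cell wall genes (9.0e-04) passed in 4 each, histones (4.9e-04) and mitochondrial genome transcripts (1.2e-04) in 3 each, and mRNA export genes in 0 (0.206). The rRNA and tRNA lists had 0 and 3 members with enough counts and were not tested.

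The first question was which RNAs were recovered with Mex67 in unstressed cells. Across genes, Mex67 replicate 2 was closest to no-tag replicate 2 of its own temperature, at 25 °C (rank correlation 0.93) and at 42 °C (0.911). The Mex67 replicates had 0.867 and 0.827 with each other. Mex67 replicate 1 was closest to another Mex67 library at 25 °C (0.88) and at 42 °C (0.835). RNA bound by Mex67 was therefore not clearly separated from background. Against the no-tag control at 25 °C, 118 of 125 ribosome biogenesis messages lay above 0, with a median of 0.50 (log2; camera adjusted p = 5.8e-17, and 0.69 with an estimated correlation). HCA4, a helicase for rRNA processing, had a log2 change of 1.71 ± 0.54 (SE from the fit of all 12 libraries, 2 compared with 2). Without no-tag replicate 1 at 25 °C that list had an adjusted p of 0.381 in the same direction. Of the 138 cytosolic ribosomal protein messages, 3 lay above 0, with a median of −0.59 (adjusted p = 1.6e-18, and 0.733 with an estimated correlation). RPL35A and RPL41A, which encode proteins of the large subunit, had −1.92 ± 0.50 and −2.07 ± 0.63. Of the 64 snoRNAs and snRNAs, 3 lay above 0, with a median of −1.92 (3.5e-26, and 0.69 with an estimated correlation). Without no-tag replicate 1 at 25 °C, the no-tag library richer in these RNAs, the median was −0.11 with 29 above 0 (0.0449). The U6 snRNA snR6 had −3.86 ± 1.32, and 0.30 without no-tag replicate 1 at 25 °C. NUP42, a nuclear pore gene of the mRNA export list, had 2.20 ± 0.56. The MEX67 message itself had −0.08 ± 0.43, with the opposite sign without no-tag replicate 1 (0.18) or Mex67 replicate 2 (0.32) at 25 °C and with total counts only (0.22). With edgeR quasi-likelihood and Benjamini-Hochberg 0 of 5245 genes passed, 204 had an unadjusted p under 0.05, and DESeq2 called 1. That gene, YAT1, a carnitine acetyltransferase gene chosen after its values were seen, had 7 counts over both no-tag libraries and 110 over both Mex67 libraries. It was also the 1 gene called without a low-count filter and the 1 called without Mex67 replicate 2 at 25 °C.

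The same question for Npl3 gave short messages. Against the no-tag control at 25 °C, 119 genes were higher and 7 lower (edgeR quasi-likelihood, Benjamini-Hochberg), with the NPL3 message itself higher by 2.26 ± 0.51 (adjusted p = 0.0418). NPL3 encodes the precipitated protein, and the series holds no library of total RNA. A higher level of its message in that strain was therefore not separated from binding. NOP15 (YNL110C, chromosome XIV, 417826 to 418488), a gene for 60S ribosome assembly, rose by 3.53 ± 0.54 (adjusted p = 0.0242). LSO2, a ribosome-bound recovery factor, rose by 3.98 ± 0.66 (0.0242), and MPP6, a nuclear exosome cofactor, by 3.59 ± 0.70 (0.034). Of 37 oxidative phosphorylation genes 9 rose and 0 fell (14 and 0 adjusted over the list alone), among them COX9, a cytochrome oxidase subunit (3.46 ± 0.68), and ATP15, an ATP synthase subunit (3.16 ± 0.57). The list had a median of 0.91 and an adjusted p of 7.9e-09 (0.69 with an estimated correlation). Of 125 ribosome biogenesis genes 11 rose (21 adjusted over the list alone), EFG1 and FYV7, both of the small-subunit pathway, by 3.97 ± 0.76 and 3.58 ± 0.76. That list had a median of 0.46 (2.1e-05, and 0.793 with an estimated correlation) and an adjusted p of 0.941 in the opposite direction without no-tag replicate 1 at 25 °C. Of 38 mRNA export genes 4 rose (9 higher and 1 lower adjusted over the list alone), including GFD1, an export factor (3.32 ± 0.76, adjusted p = 0.0464), and CDC31, of the TREX-2 complex (2.89 ± 0.61). Ribosomal protein genes rose in 5 of 138 cases (6 adjusted over the list alone), RPS29B by 2.77 ± 0.57 and RPL34A by 2.42 ± 0.53, and the proteasome gene SEM1 rose by 2.42 ± 0.53.

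HMRA1, a mating-type gene, was among the genes higher with Npl3 at 25 °C (adjusted p = 0.043). It had 2 counts over both no-tag libraries and 259 over both Npl3 libraries. STE3 also separated these groups, and the mating type of the strains was not separated from RNA bound by Npl3. Small RNAs lay lower, with 2 of 64 snoRNAs and snRNAs above 0 and a median of −2.90 (adjusted p = 1.1e-21, and 0.69 with an estimated correlation). The median was −1.15 with 6 above 0 (5.8e-08) without no-tag replicate 1 at 25 °C. SnR76 and snR79, which guide rRNA methylation and were chosen after their values were seen, fell by 3.86 ± 0.74 and by 3.05 ± 0.69, and adjusted over the list alone 1 member was higher and 50 lower. SnR19, the U1 snRNA of the spliceosome, had 2.00 ± 0.67 (adjusted p = 0.114 with edgeR, 0.000983 with DESeq2).

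Gene length separated the genes in this comparison. The rank correlation across 5134 coding genes, which are not independent replicates, was −0.503 between the log2 change and gene length. The median log2 change was 1.26 for the 135 genes of up to 300 bp and −0.43 for the 1259 longest, and genes called higher had a median length of 504 bp against 1287 bp for all. After a correction for length in each library, 1 gene was called, snR76, where 126 had been, and the median of the 119 higher genes went from 2.44 (median SE 0.543) to 1.92 (median SE 0.497). The count was 0 without no-tag replicate 1, no-tag replicate 2 or Npl3 replicate 1 at 25 °C, and 3 without Npl3 replicate 2 at 25 °C. It was 302 and 304 without either Mex67 library at 42 °C, and 300 with replicate number as a block. DESeq2 called 223 genes higher and 60 lower, and with total counts as the only scaling, which moved the median of all genes to 0.248, 205 were higher and 9 lower.

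**Figure D2:**
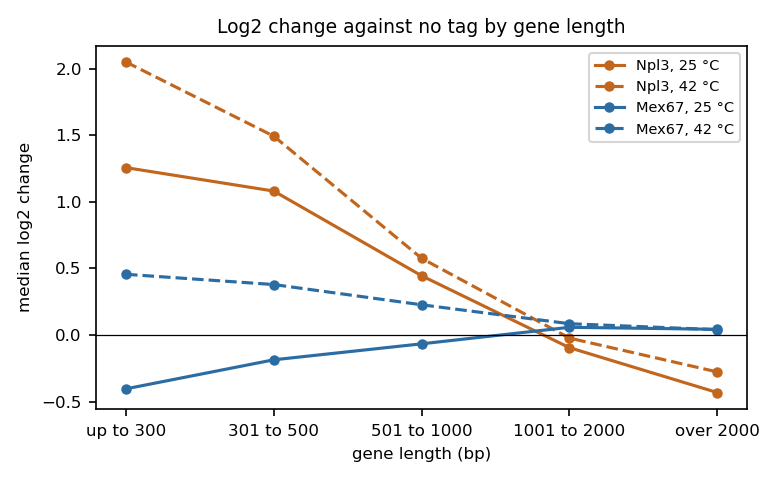
Median log2 change against the no-tag control (vertical axis) of coding genes in 5 classes of gene length (horizontal axis, bp), for both proteins and temperatures. For Npl3 at 25 °C the median went from 1.26 in genes of up to 300 bp to −0.43 in the longest class.

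After the heat shift, Mex67 was compared with the no-tag control at 42 °C to see whether stress transcripts gained. Heat shock and chaperone messages lay above 0 in 32 of 46 cases, with a median of 0.64 (camera adjusted p = 0.00699, and 0.733 with an estimated correlation). That list had an adjusted p of 0.351 without no-tag replicate 1 at 42 °C. APJ1, a chaperone gene, had 2.53 ± 0.77, HSP26 2.22 ± 1.16, HSP42 1.95 ± 0.80 and SSA4, an inducible HSP70 gene, 1.84 ± 0.86. These values rest partly on no-tag replicate 1. In no-tag replicate 2 HSP26 stood at 3544 CPM, against 8027 and 10210 with Mex67, and SSA4 at 898.5, against 2936 and 1540. HSP12 went the other way there, at 4325 CPM against 2422 and 2149 with Mex67. Messages of the translation machinery lay below 0, with 3 of 138 ribosomal protein messages above 0, a median of −1.29 and an adjusted p of 4.3e-45 (0.69 with an estimated correlation). RPS4B had −2.02 ± 0.57, SSB1, a chaperone that binds new polypeptides, −2.28 ± 0.85, EFT1 and TEF1, which encode elongation factors, −2.30 ± 0.73 and −1.77 ± 0.62. Amino acid synthesis genes had a median of −0.66 (7.0e-10, and 0.69 with an estimated correlation), ILV3 having −1.93 ± 0.58. Translation factors had −0.67 (1.4e-07, and 0.69) and ribosome biogenesis −0.46 (7.9e-07, and 0.771), NIP7 of that list having −1.80 ± 0.57. The export genes GFD1 and CDC31 had 3.13 ± 0.91 and 2.28 ± 0.72. They stood at 139 ± 118 and 111 ± 75.3 CPM (SD) in the 2 heated Mex67 libraries, so the size of these changes rests largely on 1 library. The pseudouridine guides snR191 and snR31 had −3.37 ± 1.15 and −3.06 ± 1.23, the latter 0.04 without no-tag replicate 1 at 42 °C. EdgeR quasi-likelihood called 0 genes, with 602 at an unadjusted p under 0.05, and DESeq2 called 38, of which 2 were higher and 36 lower. With total counts only, the median of all genes went from 0.125 to 0.692.

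For Npl3 at 42 °C, 343 genes were higher and 49 lower than in the no-tag control (edgeR quasi-likelihood, Benjamini-Hochberg). Of 38 mRNA export genes 8 rose and 0 fell (10 and 2 adjusted over the list alone), led by GFD1 at 5.27 ± 0.92 (adjusted p = 0.018) and CDC31 at 5.11 ± 0.74 (0.0152). The median of that list was −0.10, its mean 0.56 and its test positive (adjusted p = 0.416). SNT309 and CWC15, both genes of a splicing complex, rose by 4.67 ± 0.78 and 4.59 ± 0.84. Of 37 oxidative phosphorylation genes 14 rose and 0 fell (21 and 0 adjusted over the list alone), ATP19 by 4.63 ± 0.83, COX7 by 4.39 ± 0.70 and COX9 by 3.87 ± 0.76. The list had a median of 1.60 (5.8e-09, and 0.69 with an estimated correlation). GPX1, a glutathione peroxidase gene, rose by 3.96 ± 0.97 as 1 of 4 general stress genes that passed among all genes (0 adjusted over the list alone). CGR1, of ribosome biogenesis, rose by 3.42 ± 0.58, the mitochondrial COX2 by 2.52 ± 0.57 and MGE1, a mitochondrial cochaperone gene, by 2.14 ± 0.46. Of 33 proteasome genes 3 rose and 1 fell (10 and 1 adjusted over the list alone), with SEM1 at 3.73 ± 0.62, RPN13 at 2.71 ± 0.62 and RPN10 at −1.41 ± 0.35.

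Amino acid synthesis genes fell in 9 of 63 cases at 42 °C with Npl3, with 15 lower adjusted over the list alone and a median of −0.84 (adjusted p = 2.7e-08, and 0.69 with an estimated correlation). LEU1, ILV3 and ILV1, all of branched-chain synthesis, had −2.67 ± 0.66, −2.54 ± 0.59 and −2.43 ± 0.48. EFT1 had −2.92 ± 0.74, TEF1 −2.33 ± 0.63 and NSR1, a nucleolar protein gene, −2.82 ± 0.61. SnR30 and snR84 fell by 3.58 ± 0.98 and by 3.49 ± 0.79. SnR30 stood at 57041 ± 57167 CPM (SD) in the control at 42 °C and at 4751 ± 466 with Npl3, so the size of its fall rests largely on 1 control library. The small RNA list had a median of −1.96 (camera adjusted p = 4.3e-12, and 0.733 with an estimated correlation), and of −1.18 without no-tag replicate 1 at 42 °C. DESeq2 called 408 genes higher and 167 lower, limma voom with sample weights 305 and 134. These weights were highest for no-tag replicate 1 at 42 °C (1.34), against 0.796 and 0.872 for the heated Npl3 libraries. That fit therefore did not discount the heated control library without the heat change. Total counts only gave 643 higher and 16 lower, with the median of all genes moved from 0.102 to 0.515. After the correction for length 0 genes passed where 392 had, 1319 had an unadjusted p under 0.05, and the lowest adjusted p was 0.0638. The count was 1 without no-tag replicate 1, 0 without no-tag replicate 2 or without Npl3 replicate 1, and 667 without Npl3 replicate 2, all at 42 °C. The 1 gene called without no-tag replicate 1 was FYV7, chosen after its values were seen. Its 3 counts in the control at 42 °C were all in the library left out, so that call was made against 0 counts.

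**Figure D3:**
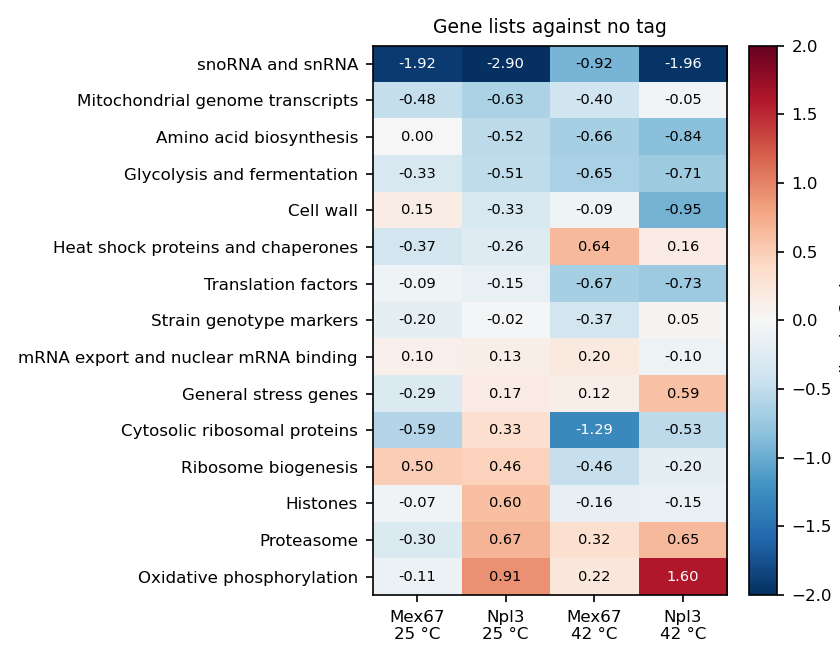
Median log2 change against the no-tag control of 15 gene lists (lines of the grid) for both proteins at both temperatures (columns), as numbers and colour. Oxidative phosphorylation messages stood at 0.91 and 1.60 with Npl3, and ribosomal protein messages at −0.59 and −1.29 with Mex67.

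Genes found with Npl3 at both temperatures were counted. The libraries of a strain at 25 °C and 42 °C come from the same cultures, so the comparisons are not independent. Of the 119 genes higher at 25 °C and the 343 higher at 42 °C, 88 were higher at both, where independent lists of these sizes would share 7.78, and 1 of the 7 and 49 lower genes was shared (0.0654). Across 5245 genes, which are not independent replicates, the log2 changes at 25 °C and 42 °C had r = 0.716, and no value for shared cultures alone was simulated. Mex67 and Npl3 were compared against the same no-tag libraries. At 25 °C their log2 changes had r = 0.266 across genes, below the 0.524 (highest of 20 simulations 0.564) that the shared control alone gave in simulated data, with a covariance of 0.195 against 0.216. At 42 °C r was 0.69 against 0.672 (highest 0.707), and the covariance was 0.854 against 0.362. The 2 control libraries could not be split between the proteins, so part of the excess of 0.492 may come from the shared controls. With 0 genes called for Mex67 at either temperature, 0 calls were shared.

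The heat change of the background was measured in the no-tag strain. HSP26 and HSP12 had log2 changes of 3.46 ± 1.23 and 3.29 ± 1.00 (adjusted p = 1 for both), and the U2 snRNA LSR1 had 2.03 ± 0.72. The replicates differed: HSP12 went from 253 to 300.4 CPM in replicate 1 and from 225 to 4325 in replicate 2. HSP26 went from 56.7 to 300.4 and from 302 to 3544, and LSR1 stood at 61509 ± 38153 CPM (SD) at 42 °C. The U6 snRNA snR6 had −4.11 ± 1.44, and 0.03 without no-tag replicate 1 at 25 °C. General stress genes had a median of 0.50 (camera adjusted p = 1.4e-06, and 0.791 with an estimated correlation). This was 0.79 with 64 of 70 above 0 without no-tag replicate 1 at 42 °C (adjusted p = 3.4e-21) and −0.51 without replicate 2 (0.0464). Without no-tag replicate 2 at 25 °C the adjusted p was 0.121. EdgeR quasi-likelihood called 0 genes, as did DESeq2, with 110 at an unadjusted p under 0.05, and the culture block called 0.

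The heat change in the Mex67 immunoprecipitation was read first from stress genes. HSP26 had a log2 change of 6.44 ± 1.41 and HSP12 of 5.46 ± 1.12 (adjusted p = 0.391 for both), and with each 42 °C library paired with the 25 °C library of its culture both rose, by 6.51 (0.00264) and 5.47 (0.027). SSA4 had 3.84 ± 0.93 (0.391, paired 0.135, DESeq2 0.000824), DDR2, a stress gene, 4.87 ± 1.54, PIR3, a cell wall gene, 2.60 ± 0.57, HSP82 1.8 ± 0.75 and HSP104 1.23 ± 0.59. Of 46 heat shock messages 34 lay above 0, with a median of 0.55 (camera adjusted p = 8.8e-05, and 0.69 with an estimated correlation). With the paired fit 2 rose among all genes, and 9 rose and 4 fell adjusted over the list alone. Of 33 proteasome messages 29 lay above 0 (median 0.44, 0.00136, and 0.69 with an estimated correlation), SEM1 having 2.26 ± 0.55. Of 70 general stress messages 64 lay above 0 (median 0.89, 4.4e-11, and 0.733 with an estimated correlation), and oxidative phosphorylation had a median of 0.68 (1.4e-04, and 0.771).

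Growth messages lay lower in the heated Mex67 libraries. Ribosomal protein messages had a median of −1.06 with 6 of 138 above 0 (camera adjusted p = 1.0e-28, and 0.69 with an estimated correlation), and with the paired fit 0 fell among all genes and 102 adjusted over the list alone. Ribosome biogenesis had −0.81 (1.1e-17, and 0.69), with YTM1 at −1.75 ± 0.45 and NIP7 at −1.93 ± 0.51. Amino acid synthesis had −0.81 (1.1e-12, and 0.69), with ILV3 at −1.86 ± 0.57, and translation factors had −0.72 (3.0e-09, and 0.69), with EFT1 at −1.68 ± 0.70. SSB1 and SSB2 had −1.87 ± 0.83 and −1.66 ± 0.70. In simulated data of this comparison, which held no effect of culture, the paired fit made 42.7 calls on average, 5.33 of them false. In the sequenced libraries edgeR quasi-likelihood called 0 genes (535 at an unadjusted p under 0.05), DESeq2 called 12, and the paired fit called 3. The third of these, YER053C-A, named after its values were seen, had 1 count over both libraries at 25 °C and 320 and 5 counts in replicates 1 and 2 at 42 °C, and it was the 1 gene called without Mex67 replicate 2 at 42 °C.

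In the Npl3 immunoprecipitation the paired fit called 46 genes, 41 higher and 5 lower at 42 °C, where the unpaired fit called 0 (edgeR quasi-likelihood). Unpaired, 576 genes had an unadjusted p under 0.05, and DESeq2 called 27. The correlation of deviations between the temperatures was 0.114 for Npl3, inside the range between different strains (−0.174 to 0.455). The paired fit was not simulated for Npl3, so these paired calls rest on the protocol's account of divided cultures. General stress genes rose in 5 of 70 cases with the paired fit (13 adjusted over the list alone), among them PAI3, a protease inhibitor gene, by 4.57 (adjusted p = 0.00354, unpaired 0.108), and NQM1, a transaldolase gene, by 4.22 (0.00354, unpaired 0.283). HSP26 rose by 4.97 (0.00523, unpaired 0.376), HSP12 by 4.56 (0.0149, unpaired 0.279) and PIR3 by 3.81 (0.00576, unpaired 0.0925). Ribosomal protein messages fell in 3 of 138 cases with the paired fit (100 adjusted over the list alone), including RPS8B at −1.96 (0.0178) and RPL9A at −2.09 (0.0431). Their median was −1.22 with 1 of 138 above 0 (camera adjusted p = 4.4e-37, and 0.69 with an estimated correlation). MET17, of sulfur amino acid synthesis, fell by 3.33 (0.0431, unpaired 0.459). The general stress list had a median of 0.90 (9.6e-09, and 0.771 with an estimated correlation), translation factors −0.70 (4.1e-10, and 0.69), ribosome biogenesis −0.38 (1.5e-07, and 0.771) and amino acid synthesis −0.44 (1.0e-05, and 0.733). The 46 heat shock messages had a median of −0.09, a mean of 0.10 and a negative test (adjusted p = 0.343), with 2 higher in the paired fit. SSA4 had 1.50 ± 0.84. GAR1, a nucleolar protein gene, and HTB2, a histone gene, had −1.35 ± 0.34 and −1.54 ± 0.56. The unpaired count was 16 without Npl3 replicate 2 at 42 °C and 2 without either Mex67 library at 42 °C, the latter being PAI3 and PIR3 in both.

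**Figure D4:**
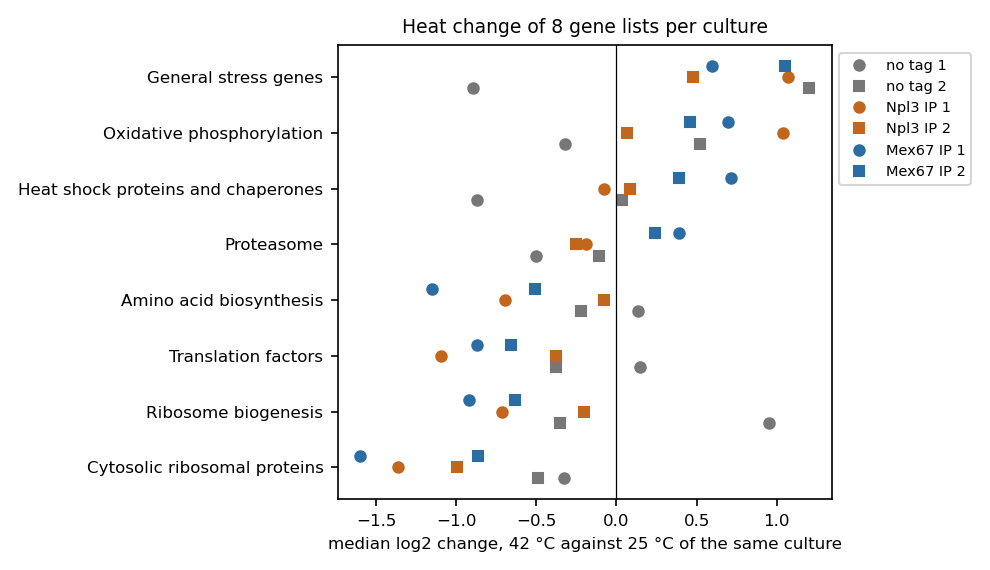
Median log2 change from 25 °C to 42 °C of 8 gene lists (vertical axis) in each of 6 cultures (horizontal axis, log2; circles, replicate 1; squares, replicate 2). General stress messages stood at −0.90 in no-tag culture 1 and at 0.48 to 1.2 in the other 5, and heat shock messages at 0.72 and 0.39 in the Mex67 cultures.

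Whether heat changed what each protein bound was asked with interactions. For heat shock messages, the change in the Mex67 libraries exceeded that in the Npl3 libraries by a median of 0.64, with 39 of 46 above 0 (camera adjusted p = 2.7e-09, and 0.69 with an estimated correlation). The change per culture was 0.72 and 0.39 with Mex67 and −0.07 and 0.08 with Npl3. For proteasome messages the difference was 0.59, with 32 of 33 above 0 (2.3e-12, and 0.69), and the change per culture was 0.39 and 0.24 with Mex67 and −0.19 and −0.25 with Npl3. Relative to the no-tag control, heat shock messages gained with Mex67 by a median of 1.03, with 37 of 46 above 0 (2.0e-07, and 0.69), and by 0.83 (2.7e-04) without no-tag replicate 1 at 42 °C. The list started below the control, with a median of −0.37 at 25 °C (adjusted p = 3.2e-04, 0.69 with an estimated correlation, 0.0542 without no-tag replicate 1), and the no-tag cultures had changes of −0.87 and 0.04, so part of the gain rests on the baseline and the control. Ribosome biogenesis messages lost with Mex67 and with Npl3, by medians of −0.97 (1.3e-26, and 0.69) and −0.60 (1.0e-15, and 0.69). The change per culture was −0.92 and −0.63 with Mex67, −0.71 and −0.20 with Npl3, and 0.95 and −0.35 in the no-tag control. Part of the loss thus rests on the control. Without no-tag replicate 1 at 42 °C the medians were −0.86 and −0.55. That fit kept the 25 °C library of the same culture, and its control still had a median of 0.11. Against the −0.35 of no-tag culture 2 alone, both Mex67 changes lay lower, and the Npl3 changes of −0.71 and −0.20 lay on either side. A loss with Npl3 beyond the control was therefore not shown for that culture. No single gene passed for any of these: edgeR quasi-likelihood and DESeq2 both called 0 genes for Mex67 against the control, for Npl3 against the control and for Mex67 against Npl3, with 186, 153 and 68 at an unadjusted p under 0.05 with edgeR and 134, 109 and 40 with DESeq2.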

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

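The 20 tests below are those in which the heat change of a gene list differed between strains, by an interaction term with an adjusted p under 0.05 in camera. They were planned, and all of them were lost with an estimated correlation between genes (0.69 or more). The tests of explanations for the 3 patterns that follow were chosen after the result was seen.

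Between Mex67 and Npl3, heat shock messages (2.66e-09) and proteasome messages (2.28e-12) gained with Mex67. Amino acid biosynthesis (0.00237) and ribosome biogenesis (1.18e-04) lost and histones (0.0206) gained with Mex67. Amino acid biosynthesis had 0.522, 0.519, 0.149 and 0.104 without Npl3 replicate 2 at 25 °C, Mex67 replicate 1 at 25 °C, Npl3 replicate 2 at 42 °C and Mex67 replicate 1 at 42 °C. Ribosome biogenesis had 0.961 and 0.166 without the last 2 of these libraries. Histones had 0.712, 0.933, 0.191 and 0.384 without Npl3 replicate 2 and Mex67 replicate 1 at 25 °C, and Npl3 replicate 2 and Mex67 replicate 2 at 42 °C.

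Between Mex67 and the no-tag control, amino acid biosynthesis (1.74e-09), ribosome biogenesis (1.35e-26), translation factors (1.89e-05) and ribosomal protein messages (1.38e-11) lost, and heat shock (1.96e-07), proteasome (1.20e-05) and general stress messages (0.00346) gained. Ribosomal protein messages had 0.0652 without Mex67 replicate 2 at 25 °C and 0.945, reversed, without Mex67 replicate 1 at 42 °C. General stress messages had 0.213 without no-tag replicate 1 at 25 °C. They reversed, at 0.784, 0.368 and 0.966, without no-tag replicate 1 at 42 °C, Mex67 replicate 2 at 25 °C and Mex67 replicate 1 at 42 °C.

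Between Npl3 and the no-tag control, ribosomal protein messages (1.94e-17), ribosome biogenesis (1.03e-15), translation factors (1.49e-06), amino acid biosynthesis (2.83e-04), histones (0.0151) and cell wall genes (0.0223) lost, and general stress messages (0.0192) and snoRNAs and snRNAs (0.0261) gained. Amino acid biosynthesis had 0.0523, 0.0782 and 0.462 without no-tag replicate 2 and Npl3 replicate 1 at 25 °C and no-tag replicate 1 at 42 °C. Histones had 0.106 to 0.425 without no-tag replicate 2 or Npl3 replicate 2 at 25 °C, or Npl3 replicate 2 at 42 °C, where it was 0.145, and 0.101 without no-tag replicate 1 at 42 °C. Cell wall genes had 0.212, 0.2, 0.0778 and 0.41 without no-tag replicate 1 and Npl3 replicate 1 at 25 °C, and no-tag replicate 2 and Npl3 replicate 1 at 42 °C. General stress messages had 0.579 and 0.14 without no-tag replicate 1 and Npl3 replicate 2 at 25 °C, and reversed, at 0.444 and 0.946, without no-tag replicate 1 and Npl3 replicate 1 at 42 °C. Small RNAs reversed, at 8.19e-05 and 0.345, without no-tag replicate 1 at 25 °C and no-tag replicate 2 at 42 °C, and had 0.152 and 0.0721 without Npl3 replicate 2 at 25 °C and Npl3 replicate 1 at 42 °C.

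Heat shock and proteasome messages shifted more with Mex67 than with Npl3. A single library was argued against, since the highest adjusted p of the heat shock list without any 1 library was 0.00249. A trend with gene length was argued against by the length-corrected adjusted p of 2.97e-09 in the same direction. Variation that the list's genes share between libraries may be the source, but its test could not tell: the adjusted p was 0.69 with an estimated correlation, and 0 of the 150 list tests passed that way. A difference between the proteins in the RNAs they bind under heat stays open and was not separated from this.

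The heated no-tag replicate 1 did not reach the heat change of the other heated libraries: its general stress genes had a median of −0.898, and HSP26 went from 56.7 to 300.4 CPM. It also stood apart in make-up. Protein-coding genes held 55.2% of its counts (next lowest library 69.9%), snoRNAs and snRNAs 30.4% (next highest 21.8%) and its top 10 features 34.6% (next highest 22%). The quality of its RNA was not tested. Low depth was argued against, since the other heated no-tag library, thinned to 87741 counts in 20 draws, kept a median change of 0.997 or more. An exchange of labels with the unheated no-tag library of that number was argued against by 56.7 CPM of HSP26 there, below the 3544 of the lowest other heated library. A sample that had not responded, or a wrong temperature label, stays a candidate explanation, though it had no test of its own. HSP26 at 300.4 CPM, which is part of the pattern itself, lay inside the range of the 25 °C libraries (56.7 to 633). That value lay above the library's own culture at 25 °C, so a weak response is not excluded. A difference in strain was not excluded, since the labels name 2 strains for the no-tag control. LEU2, chosen after its values were seen, stood at 1374 and 868 CPM in no-tag replicate 1 at 25 °C and 42 °C. In no-tag replicate 2 it stood at 11.8 and 16. The labels assign no library to a strain, so no biological explanation was tested.

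Short coding genes led the RNAs found with Npl3. A length trend that both proteins' immunoprecipitations carry alike was argued against, since the lowest rank correlation with length among the 4 Mex67 libraries was −0.005, above the highest of the 4 Npl3 libraries (−0.376), with SDs of 0.163 and 0.0595, which does not exclude a weaker shared trend. A first test of it, the correlation of the Mex67 change at 25 °C with length, was undecided (0.141, −0.144 to 0.29 without 1 library; at 42 °C −0.139, −0.186 to 0.00278, the sign of the Npl3 trend), and the test by library replaced it after that was seen. Depth was argued against as the source of the length trend by a correlation of −0.495 after thinning the other 11 libraries to 354440 counts without no-tag replicate 1 at 42 °C. The calls did not stay: 0 genes passed for Npl3 at either temperature after thinning, where 84 and 1 passed without that library at full depth. A length trend as the whole of the change stays open: after its correction the 119 genes higher at 25 °C had a median of 1.92 (SE 0.497) where they had 2.44 (SE 0.543), all 119 still above 0. These genes were selected for a high change in the same counts, so the question is not decided by their median and sign after the correction. After the correction 84 genes at 25 °C and 557 at 42 °C had an adjusted p under 0.1 (edgeR quasi-likelihood). An unadjusted p under 0.05 was left in 841 and 1319. These counts cover all tested features and both directions, so they do not decide it for the short genes. The lowest adjusted p at 25 °C had been 0.0242 and was 0.0262 after the correction. Why the other calls ended was not tested. Shorter fragments in the Npl3 libraries and a preference of Npl3 for short messages therefore could not be told apart.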

How the results depend on the processing

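Limma voom with sample weights, bias-adjusted deviances, both length-corrected fits and fry were chosen after the data were seen. The heat change of the no-tag control and both interactions with it gave 0 calls under every alternative run. The 24 RNA class shares moved by less than 1 SD, which leaving out 1 of 2 libraries fixes by construction.

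With DESeq2 the counts were 1 (Mex67 at 25 °C), 283 (Npl3 at 25 °C), 38 (Mex67 at 42 °C), 12 (heat, Mex67) and 27 (heat, Npl3), where edgeR had 0, 126, 0, 0 and 0. With total counts only, Npl3 had 214 at 25 °C and 659 at 42 °C, where the fit with TMM had 126 and 392. Without a low-count filter the counts were 1 (Mex67 at 25 °C), 263 (Npl3 at 25 °C) and 9 (heat, Npl3). With only the groups compared they were 228 (Npl3 at 25 °C) and 7 (heat, Npl3), from fewer libraries. With replicate number as a block, Npl3 at 25 °C had 300 and the Npl3 heat change 10. The culture block gave 3 (heat, Mex67) and 46 (heat, Npl3), with length-corrected offsets 4, 77 and 1 (heat, Mex67 against Npl3), and pairing changed no other count. Length-corrected offsets gave 1 (Npl3 at 25 °C) and 0 (Npl3 at 42 °C). Except where stated, the cause was not tested.

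Leaving out each library in turn gave 0 to 304 calls for Npl3 at 25 °C, 0 to 667 for Npl3 at 42 °C, 0 to 1 for Mex67 at 25 °C, 0 to 1 for the Mex67 heat change, 0 to 16 for the Npl3 heat change and 0 to 1 for the difference of the heat changes. A group left with 1 library was assumed to vary like the others, and the cause was not tested.

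Of 150 list tests 77 passed, 0 with an estimated correlation and 0 with fry, which asks whether a list's own genes move. Without 1 library 71 to 83 passed, of 160 tests in 11 of the 12 fits and of 150 in the other. Of the 77, 65 to 74 were called again in either direction, some of them reversed (below). In the Mex67 heat change, heat shock messages had 0.429 and proteasome messages 0.32 with fry, and both had 0.69 with an estimated correlation. In the difference between Mex67 and Npl3 they had 0.474 and 0.301 with fry, and 0.69. Lists reversed in 14 fits. For ribosomal proteins with Npl3 at 25 °C the length-corrected adjusted p was 0.911. The other 13 left out 1 library and are given after the range of the adjusted p over the fits that kept the direction. With Mex67 at 25 °C general stress had 4.46e-17 to 0.695 and reversed at 0.0468. With Npl3 at 25 °C ribosome biogenesis had 3.25e-17, under 0.05 in all others, and reversed at 0.941. In the no-tag heat change general stress had 3.36e-21 to 0.121 and reversed at 0.0464, and ribosome biogenesis had 1.11e-24 to 0.0731 and reversed at 0.0268. In the Npl3 heat change mitochondrial transcripts had 7.17e-07 to 0.563 and reversed at 0.785. In the interaction of Mex67 with the control ribosomal proteins had 1.82e-42 to 0.0652 and reversed at 0.945, and general stress had 8.19e-11 to 0.213 and reversed at 0.368, 0.784 and 0.966. In that of Npl3 general stress had 1.71e-09 to 0.579 and reversed at 0.444 and 0.946, and small RNAs had 8.85e-14 to 0.152 and reversed at 8.19e-05 and 0.345. The cause was not tested.

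The correlation of Mex67 and Npl3 changes at 25 °C, 0.266, was 0.17 with protein-coding genes only, 0.31 with a mean of at least 50 counts and 0.351 length-corrected, and at 42 °C, 0.69, it was 0.718 length-corrected. Of 89 gene results in the text 4 changed sign. Without 1 library, MEX67 with Mex67 at 25 °C (−0.08) had −0.597 to 0.323, above 0 without no-tag replicate 1 (0.183) or Mex67 replicate 2, and 0.221 with total counts only. SnR6 there (−3.86) had −4.81 to 0.296, and in the no-tag heat change (−4.11) −5.03 to 0.0302, both above 0 without no-tag replicate 1 at 25 °C. SnR31 with Mex67 at 42 °C (−3.06) had −4.18 to 0.0387, above 0 without no-tag replicate 1 at 42 °C. The cause was not tested. The smallest library, 87741 counts, limits all comparisons with the no-tag control at 42 °C.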

Other observations

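With each heated Npl3 library paired with its culture at 25 °C, JEN1, a lactate transporter gene, had a log2 change of 4.52 (adjusted p = 0.00354), CAT8, a transcription factor gene for growth without glucose, 3.33 (0.0039), PCK1, of glucose synthesis, 3.50 (0.0365), ALD3, an aldehyde dehydrogenase gene, 3.09 (0.0178) and REG2, a phosphatase subunit gene, 4.69 (0.00354). These genes were chosen after their values were seen, and without pairing their adjusted p-values were 0.279, 0.334, 0.232, 0.283 and 0.165 with edgeR and 0.000561, 0.024, 0.0211, 0.0296 and 0.00289 with DESeq2. No list for what these genes do was tested. ALD3 stood at 28.3 and 11.8 CPM in the no-tag libraries at 25 °C and at 33.4 and 183 at 42 °C. JEN1 stood at 13.8 and 6.39 CPM at 25 °C and at 468 and 95.4 at 42 °C with Npl3, and at 20.6 and 35, then 119 and 53.8, with Mex67.

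The U1 snRNA was 1 of 2 among 64 snoRNAs and snRNAs above 0 with Npl3 at 25 °C, the other being the U2 snRNA LSR1 at 0.27 (adjusted p = 0.849). SnR19 had 20590 and 36570 CPM with Npl3 at 25 °C and 47490 and 37160 at 42 °C. The no-tag libraries had 7844 and 6466 CPM at 25 °C and 6424 and 12590 at 42 °C, and the 4 Mex67 libraries had 7061 to 12070. It was the feature with the most counts in 3 of the 4 Npl3 libraries and in Mex67 replicate 1 at 42 °C.

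Genes of a single mating type differed between replicates of the same group. A difference in strain was not separated from this, neither for the no-tag group, whose labels name 2 strains, nor for the other groups. MFA2, a pheromone gene of a cells, stood at 18 and 788 CPM in Npl3 replicates 1 and 2 at 25 °C and at 52 and 627 at 42 °C. The alpha factor gene MF(ALPHA)1 stood at 1078 and 60.6 in the Mex67 replicates at 25 °C and at 877 and 681 in the no-tag replicates. LEU2 stood at 1078 and 2.33 in the Mex67 replicates at 25 °C, and URA3 at 1052 and 1183 in the Npl3 replicates against 333 and 20.7 in the no-tag replicates. No explanation for these differences was tested.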
